A study of Mus musculus with 9 samples.

How the data were processed

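Poly(A) RNA from the hippocampus of 9 male mice, 3 per group, had been sequenced as paired-end reads on an Illumina instrument, per the labels' protocols. The deposited table holds 2 values per gene and library. The counts are the authors' raw read counts per gene, whole numbers with no normalization, per the file headers. The FPKM values are the authors' own, and in the deposited table they equal each count divided by a fixed length per gene and by the library's total. Per the submitters' processing notes the tools were HISAT2 2.0.4, StringTie 1.3.3b, edgeR 3.2.0 and Bowtie2, with the mouse build GRCm39. Their roles, the counting program, the annotation release and the strand setting are not given in the sources used here. Without strand, reads of a gene and of an overlapping antisense gene cannot be told apart. FPKM values were used only to check the counts.

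The table lists 57180 genes, of which 25887 have no counts in any library, and 523 have no symbol. All columns were mapped to samples by the library names in the labels. Groups and replicate numbers follow the sample titles, which call the replicates biological. Totals per library were 14751054 to 18827093 counts, so 3 counts equal 0.159 to 0.203 CPM. Such floors cover counting error only, since PCR copies are not independent molecules.

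Genes were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (17550), libraries were scaled by TMM factors (0.960 to 1.01), and a quasi-likelihood model with robust dispersion was fitted to all 9 libraries with the group as the only term, so that the 3 groups share one estimate of the spread (common dispersion 0.0196). Each pair of groups was compared with a two-sided quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors are those implied by the F statistic, with a median of 0.139 on the log2 scale in both comparisons with Model. Levels are normalised CPM given as mean ± SD. A prior count of 2 was used for log2 CPM. Every adjusted p of a gene comes from edgeR unless another tool is named, and every adjusted p of a list from camera in limma 3.58.1 unless fry is named.

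The design, the alternatives, the rule for named genes and 35 gene lists were fixed before the data were examined. The lists cover lipid and S1P metabolism, synapses, neuronal activity, cell types of the hippocampus and of neighbouring tissue, stress responses and mitochondria. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists, and again with an estimated correlation and with fry. Members were also adjusted over the list alone. Named genes were, per comparison, the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap, up to 2 members per direction of each list discussed, and 14 genes named in every comparison (Apoe, 7 S1P genes, Dlg4, Syn1, Bdnf, Draxin, Itpr3 and Disc1). Where fewer than 10 genes passed, the 5 with the smallest p were named. Unannotated genes and pseudogenes were left out of the largest changes.

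Near-identical genes were found with BLAST 2.17.0 by aligning the transcripts of the GENCODE M21 annotation (GRCm38), matched by gene ID only, since this reference is of another build than the deposited coordinates. All coordinates in the text are those of the deposited table on GRCm39. The reference held 51884 of the genes, and a pair counted as near-identical at 97% identity over at least 150 bases and 50% of the shorter transcript. Of 29433 genes with counts that could be searched, 3023 had such a copy, and 1860 genes with counts were not in the annotation.

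Simulated counts with 200 changed genes among the real genes were used to test the procedure. In MAN@SKI II against Model (17300 genes) 29.9% of 1.5-fold, 74.6% of 2-fold and 87.9% of 4-fold changes were recovered, with 9 false calls among 137. In Model against Con (17288 genes) the shares were 43.3%, 67.2% and 87.9%, and in MAN@SKI II against Con (17279 genes) 35.8%, 67.2% and 92.4%. In 20 simulations of unchanged groups with independent genes, camera called 3 of 700 lists. Comparisons that share a control group were set against 20 simulations per setting.

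The alternatives were RLE factors (median of ratios), no factors, no filter, a filter of at least 1 CPM in at least 3 samples, DESeq2 1.42.0, limma-voom, the 6 compared libraries alone, a threshold of 1 on the log2 scale, the replicate number as a term, and each library left out in turn. Other pseudocounts and a filter on FPKM, meant for a deposited table without counts, were not run because the authors deposited counts. Added after seeing the data were the removal or summing of near-identical genes and the mean of the choroid plexus genes as a covariate. Figures were drawn in Python 3.11.15.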

Results

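RNA was sequenced from the hippocampus of 9 male mice, with 3 mice in each of 3 groups. The Con group were C57BL/6J mice, a standard inbred strain, given vehicle. The Model group were BTBR T+ Itpr3tf/J mice (BTBR), an inbred strain with low sociability and repetitive behaviour that serves as a mouse model of autism, also given vehicle. The MAN@SKI II group were BTBR mice given MAN@SKI II, a nanomicelle directed to the brain that the labels describe as an inhibitor of sphingosine-1-phosphate (S1P), a signalling lipid made by sphingosine kinases. Treated mice received 40 mg/kg per day into the tail vein for 7 days, starting at 5 weeks of age. Hippocampi were taken at 6 weeks of age, after behavioural testing. The labels name the vehicle as saline in one field and as PBS in another. The series title names the hippocampal APOE/S1P axis and synaptic deficits as its subject. Total counts per library lay between 14751054 (MAN@SKI II 2) and 18827093 (Con 3), at which 3 counts correspond to 0.159 to 0.203 CPM, the unit of all levels below (counts scaled to the library total).

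The first principal component of log2 CPM held 42.7% of the variance and placed the Con libraries between -49.8 and -43.4 and the 6 BTBR libraries between 16.1 and 34.9. MAN@SKI II 2 stood apart on the second component (14.8% of the variance), at 49.9, with the other 8 libraries between -16.4 and 4.17. Mitochondrially encoded genes took 9.63% of its counts, against 6.26% to 7.15% in the other libraries. Its Spearman correlations with the other 5 BTBR libraries were 0.982 to 0.985, whereas the 10 pairs among those libraries had 0.990 to 0.991. Con libraries had 0.972 to 0.983 with the BTBR libraries, a range that overlaps that of MAN@SKI II 2.

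The comparison of Model with Con asked how hippocampal expression differs between the model strain and the control strain. Serpina3n, a secreted serine protease inhibitor typical of reactive astrocytes, was at 214 ± 9.86 CPM in Model and 60.0 ± 1.88 CPM in Con (mean ± SD, n = 3 each), a log2 fold change of 1.84 ± 0.08 (SE). Lgr6, a receptor for R-spondins, rose from 3.54 ± 0.0876 to 17.6 ± 1.65 CPM, and Pla2g4e, a cytosolic phospholipase A2 family enzyme, rose from 7.49 ± 0.268 to 28.9 ± 3.13 CPM. Gabra2, a GABA-A receptor subunit, rose from 96.7 ± 9.10 to 214 ± 23.0 CPM. Mobp, a structural protein of myelin, fell from 1166 ± 100.3 to 556 ± 17.6 CPM. On GRCm39, Serpina3n lies on chromosome 12 from 104372988 to 104380588, Pla2g4e on chromosome 2 from 119996893 to 120075816, Gabra2 on chromosome 5 from 71114940 to 71253192, and Mobp on chromosome 9 from 119978773 to 120010550. Of 17550 genes tested by edgeR's quasi-likelihood test, 546 were higher and 794 lower in Model at an adjusted p under 0.05, and 205 and 361 of these differed by at least 1 on the log2 scale. The count of 1340 called genes became 830 without Con 1, 880 without Con 2, 850 without Model 1, 872 without Model 3 and 2226 without MAN@SKI II 2. It was 2073 when the 6 compared libraries were fitted alone, and 124 with the mean of the choroid plexus genes as a covariate, a setting chosen after seeing the data.

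**Figure D1:**
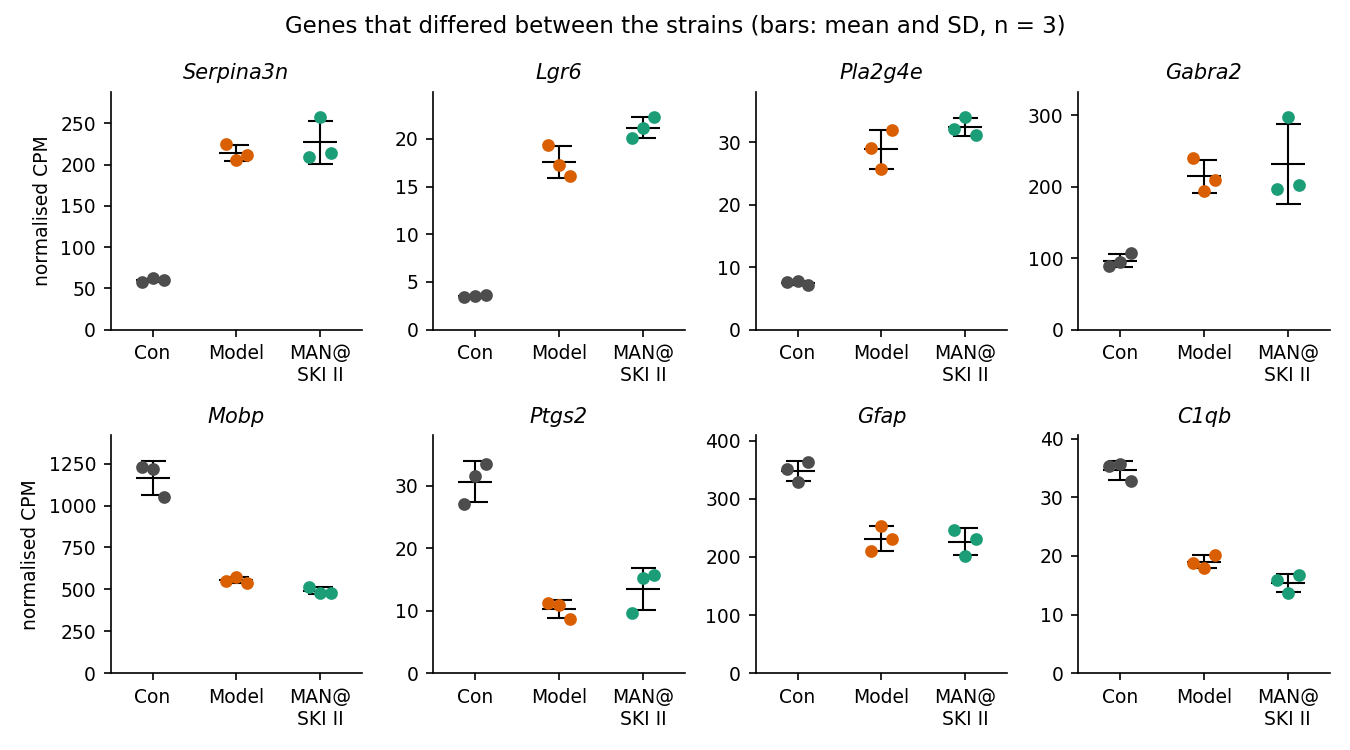
Normalised CPM of 8 genes in each library (points), with the mean and SD of each group (bars, n = 3). Serpina3n, Lgr6, Pla2g4e and Gabra2 were higher, and Mobp, Ptgs2, Gfap and C1qb lower, in all 6 BTBR libraries than in all 3 Con libraries.

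Genes of several cell types were lower in Model than in Con. All 15 myelin and oligodendrocyte genes tested had negative values (median log2 fold change -0.51). Of these genes, 9 fell over all genes tested and 14 fell when adjusted over the list alone. The list was called by camera (adjusted p = 1.11e-12), with adjusted p = 0.489 with an estimated correlation. Under the choroid plexus covariate its median was -0.13 and the call was lost (adjusted p = 0.0560). Among 19 microglial identity genes, 5 fell, and 8 fell when adjusted over the list alone. The fallen genes included C1qb, a subunit of complement C1q, at -0.86 ± 0.10, and Fcrls, an Fc receptor-like microglial protein, at -0.90 ± 0.15. The microglial list had a median of -0.20 (-0.13 without Con 3) and a camera adjusted p = 0.00156, with adjusted p = 0.489 with an estimated correlation. Of 10 dentate gyrus granule cell genes, 3 fell, and 8 fell when adjusted over the list alone, with a median of -0.43 and a camera adjusted p = 2.91e-06 (adjusted p = 0.602 with an estimated correlation). Lct fell by 0.89 and Trpc6, a cation channel, fell by 0.92 on the log2 scale. Fry called the myelin, microglial and dentate gyrus lists as lower too (fry adjusted p = 0.00791, 0.00791 and 0.0200). Astrocyte identity genes were not called as a list by camera (adjusted p = 0.257) but were called as lower by fry (fry adjusted p = 0.00990). Of 14 astrocyte genes 3 fell, among them Gfap, the astrocyte intermediate filament, from 348 ± 17.3 to 231 ± 21.7 CPM, and Aldoc, an aldolase of astrocytes, from 665 ± 34.3 to 511 ± 38.2 CPM. In the list of CA field pyramidal cell genes, 2 of 15 rose and 3 fell, including Iyd at -2.15 ± 0.26 and Spink8 at -1.52 ± 0.16. That list had a median of 0.04, a mean of -0.22 and a camera direction of down (adjusted p = 0.644), so these differ in sign. Ptgs2, the inducible cyclooxygenase, fell from 30.6 ± 3.29 to 10.3 ± 1.45 CPM.

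Transcripts of the choroid plexus, a tissue that lies against the hippocampus, were much lower in Model. Ttr, which encodes transthyretin and is its most abundant marker, was at 2232, 1259 and 824 CPM in Con 1 to 3, at 13.5, 257 and 12.9 CPM in Model 1 to 3, and at 17.0, 19.3 and 313 CPM in MAN@SKI II 1 to 3. Of the 15 choroid plexus genes tested, 8 fell in Model and 13 fell when adjusted over the list alone (median log2 fold change -3.16, camera adjusted p = 3.24e-11). The list had an adjusted p = 0.602 with an estimated correlation, and it was called by fry (fry adjusted p = 0.0390). Folr1, a folate receptor, was at 0.405 ± 0.102 CPM in Model and 3.60 ± 2.02 CPM in Con. Ependymal genes moved with them: 1 of 9 fell, and 4 fell when adjusted over the list alone, with a median of -0.92 and a camera adjusted p = 0.00867 (adjusted p = 0.872 with an estimated correlation). The ependymal call was lost by fry (fry adjusted p = 0.127), without Con 1 (adjusted p = 0.0564) and without Model 3 (adjusted p = 0.0597). Its median was -1.41 without Model 2, and its direction turned, with a median of 0.49, under the choroid plexus covariate.

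Some of the largest falls were in genes with near-identical copies, whose counts are uncertain. Rpl14, a ribosomal protein gene, was at 72.5 ± 0.699 CPM in Con and 2.96 ± 0.454 CPM in Model, but summed with its near-identical copy Rpl14-ps1 the values were 143 ± 4.49 and 149 ± 9.36 CPM (log2 fold change 0.06, adjusted p = 0.889). Rpl29 was at 49.2 ± 1.40 and 2.77 ± 0.431 CPM, and its family of 19 members summed to 74.6 ± 1.295 and 109 ± 3.61 CPM, the opposite direction (0.55, adjusted p = 0.0127). Cox7c, a cytochrome c oxidase subunit, had a log2 fold change of -1.52 ± 0.20 alone and of -0.43 as a family of 3 (adjusted p = 0.0592). No near-identical copy with counts was found for Ccl21a, Pttg1 or Eps8l1. Ccl21a, a chemokine gene, was at 10.7 ± 1.11 CPM in Con and 0.0751 ± 0.0849 CPM in Model, where no library held more than the floor of 3 counts. Pttg1, which encodes securin, fell from 18.6 ± 0.739 to 0.348 ± 0.0643 CPM, and Eps8l1, an actin regulator, fell from 11.9 ± 3.35 to 0.599 ± 0.378 CPM.

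RNA levels of the S1P pathway genes did not differ detectably between Model and Con. Of 14 S1P kinases, lyase, phosphatases, transporters and receptors tested, 0 were called by edgeR, DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.674 for the list). The log2 fold changes were -0.38 ± 0.42 for Sphk1, 0.07 ± 0.09 for Sphk2, 0.01 ± 0.11 for the lyase Sgpl1, 0.09 ± 0.08 for S1pr1, 0.0032 ± 0.29 for S1pr2, 0.10 ± 0.10 for S1pr3 and -0.23 ± 0.10 for S1pr5. Sphk1 took 0.02 without Con 3. Sgpl1 took -0.0035 without Con 3 and -0.06 without Model 3, and S1pr2 took -0.08 without Con 1, -0.04 without Con 2, -0.21 without Model 2 and -0.10 without Model 3. Apoe, the main lipid carrier of the brain (chromosome 7, 19430034 to 19433113), was at 1061 ± 89.3 CPM in Model and 920 ± 155 CPM in Con (0.21 ± 0.21, edgeR adjusted p = 0.693). Of 26 ceramide and sphingomyelin enzymes, 1 rose and 2 fell. The riser was Acer2, a ceramidase, from 6.12 ± 0.818 to 17.6 ± 5.28 CPM. Lpl, lipoprotein lipase, rose from 50.9 ± 6.80 to 112 ± 7.78 CPM, and Sc5d, an enzyme of cholesterol synthesis, fell from 83.7 ± 0.787 to 54.3 ± 2.32 CPM.

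Synaptic genes showed few strain differences. Of 32 genes of the excitatory postsynapse, 0 were called by edgeR and limma-voom and 1 by DESeq2, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.755). Dlg4, the scaffold PSD-95, was at 674 ± 68.6 CPM in Model and 707 ± 32.2 CPM in Con, and Syn1, synapsin I, at 739 ± 10.1 and 723 ± 36.4 CPM. In the presynaptic list 1 of 26 genes rose, Cplx2, a complexin of vesicle release, at 0.29 ± 0.06 (camera adjusted p = 0.343 for the list). Of 15 GABA receptor genes 1 rose, Gabra2, at 1.15 ± 0.16 (camera adjusted p = 0.208 for the list). Bdnf, a neurotrophin, was at 35.7 ± 2.95 CPM in Model and 45.3 ± 3.66 CPM in Con and was not called (-0.34 ± 0.10, adjusted p = 0.0775), whereas its adjusted p was 0.0293 without MAN@SKI II 2, 0.0490 by DESeq2 and 0.0269 with the 6 compared libraries alone. Of the genes known to carry BTBR variants, Draxin, an axon guidance gene (chromosome 4, 148182894 to 148215155), fell from 2.58 ± 0.360 to 0.786 ± 0.326 CPM. Itpr3 had a value of -0.28 ± 0.18 (adjusted p = 0.465) and Disc1 of -0.63 ± 0.26 (adjusted p = 0.202). In the list of 35 autism risk genes, 1 fell over all genes tested and 0 changed when adjusted over the list alone, with 6 at an unadjusted p under 0.05, 2 called by DESeq2 and 1 by limma-voom.

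**Figure D2:**
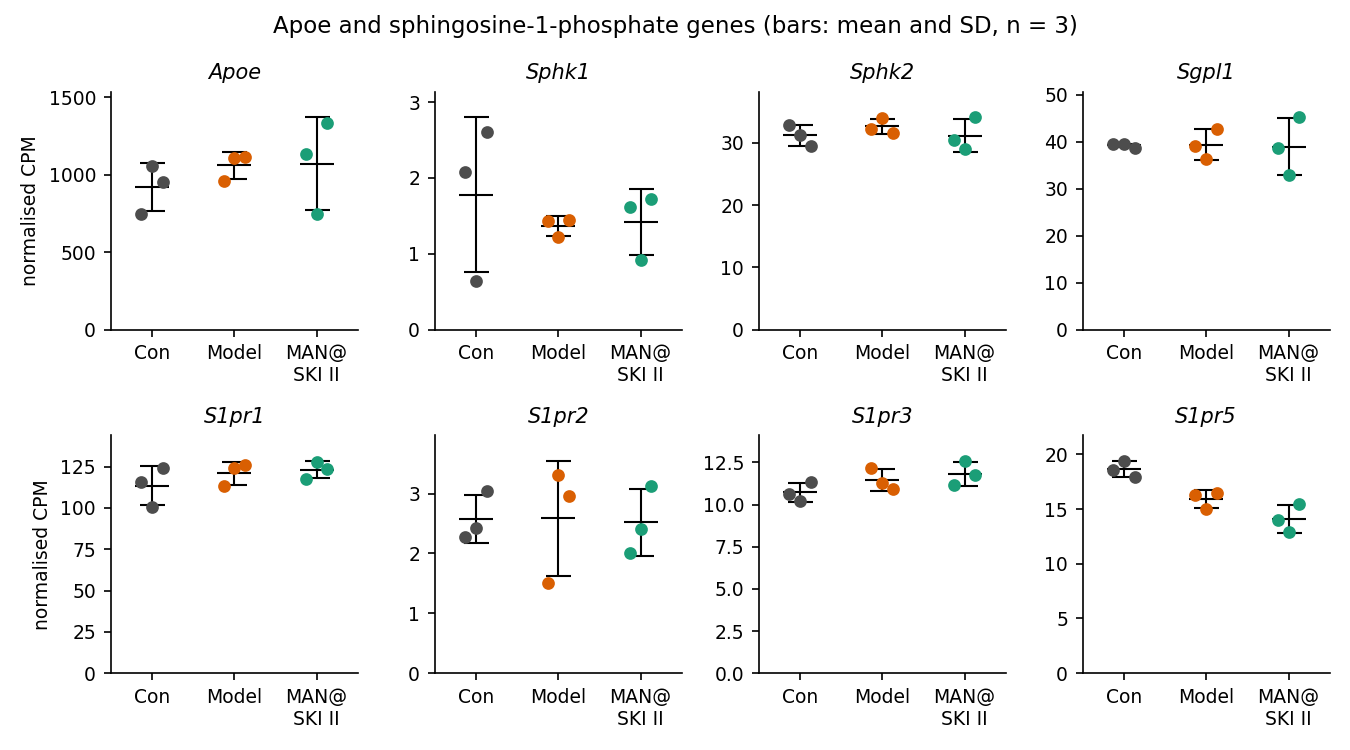
Normalised CPM of Apoe and 7 genes of S1P metabolism and signalling in each library (points), with the mean and SD of each group (bars, n = 3). S1pr5 was the only one of the 8 genes called in a comparison, MAN@SKI II against Con (adjusted p = 0.0317).

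The comparison of MAN@SKI II with Model asked what treatment with the S1P inhibitor changed within BTBR mice. Immediate early genes, which neurons induce on activity, had a lower mean level in the 3 treated mice than in the 3 Model mice. Of 21 tested, 18 had negative log2 fold changes (median -0.41, and -0.36 without MAN@SKI II 2), and 8 fell when adjusted over the list alone: Nr4a1, Nr4a2, Dusp1, Egr1, Fos, Arc, Junb and Egr4. Fos had a log2 fold change of -1.14 ± 0.33, Dusp1, a phosphatase that ends MAP kinase signalling, of -0.67 ± 0.18, Nr4a1, a nuclear receptor, of -0.58 ± 0.14, and Arc, a regulator of AMPA receptors, of -0.56 ± 0.17 (SE). The list's mean log2 CPM was 5.205 ± 0.136 in Con, 5.368 ± 0.169 in Model and 4.958 ± 0.213 in MAN@SKI II (SD, n = 3 each). It was called by camera (adjusted p = 1.62e-15), with adjusted p = 0.361 with an estimated correlation, and the list mean gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 mice can give. None of the 21 genes was called over all genes tested: edgeR, DESeq2 and limma-voom each called 0, with 13 at an unadjusted p under 0.05.

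Over all 17550 genes, 0 were called by edgeR between MAN@SKI II and Model, and limma-voom also called 0. DESeq2 called 17 genes, 10 higher and 7 lower, and 846 genes (4.82%) had an unadjusted p under 0.05 by edgeR. Impdh1, an enzyme of guanine nucleotide synthesis (chromosome 6, 29200433 to 29216363), had the smallest adjusted p, 0.0697, at 32.3 ± 1.28 CPM in MAN@SKI II and 49.2 ± 1.45 CPM in Model (log2 fold change -0.60 ± 0.07). It was called by DESeq2 (adjusted p = 1.11e-07), with no normalisation factors (0.0494), with no filter (0.0333), without Model 3 (0.0496), without MAN@SKI II 2 (0.0119) and without MAN@SKI II 3 (0.0276). Srp72, a subunit of the signal recognition particle, was at 68.3 ± 8.08 CPM in MAN@SKI II and 102 ± 4.21 CPM in Model (adjusted p = 0.188, and 0.00621 without MAN@SKI II 2). Usp45, a deubiquitinase, was at 59.6 ± 13.03 and 30.4 ± 2.71 CPM (adjusted p = 0.188, and 0.000173 without MAN@SKI II 2). Metap2, a methionine aminopeptidase with the near-identical copy Gm9333, had a value of 0.39 ± 0.07 (adjusted p = 0.592), and Gm16701, an uncharacterised gene, of 1.76 ± 0.32 (adjusted p = 0.613). Both Srp72 and Usp45, and Metap2, were called by DESeq2. The count called by edgeR was 1 without Con 2, 3 without Model 2, 9 without Model 3, 6 without MAN@SKI II 1, 6 without MAN@SKI II 2 and 9 without MAN@SKI II 3. The gene called without Con 2 was Ywhah, a 14-3-3 protein, which was also the 1 gene called with the 6 compared libraries alone, and those called without Model 2 were Atp8a1, AW554918 and Gm4199; all 4 were chosen after their values were seen.

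RNA levels of the S1P genes and Apoe did not differ detectably with treatment. The counts do not measure S1P itself, kinase activity or protein. Of 14 S1P genes, edgeR, DESeq2 and limma-voom called 0, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.800 for the list). Apoe was at 1072 ± 299 CPM in MAN@SKI II and 1061 ± 89.3 CPM in Model (0.02 ± 0.21, edgeR adjusted p = 0.994). The log2 fold changes were 0.06 ± 0.44 for Sphk1, -0.07 ± 0.09 for Sphk2, -0.01 ± 0.11 for Sgpl1, 0.03 ± 0.08 for S1pr1, -0.05 ± 0.30 for S1pr2, 0.05 ± 0.10 for S1pr3 and -0.17 ± 0.10 for S1pr5. Single libraries turned the sign of several of these. Apoe took -0.05 without Model 1, -0.03 without MAN@SKI II 1 and -0.17 without MAN@SKI II 3, and Sphk1 took -0.01 without Model 2, -0.04 without MAN@SKI II 1 and -0.09 without MAN@SKI II 3. Sgpl1 took 0.05 without Model 3 and 0.09 without MAN@SKI II 2, S1pr1 took -0.02 without Model 1 and -0.0027 without MAN@SKI II 2, and S1pr3 took -0.00012 without MAN@SKI II 2. S1pr2 took 0.17 without Model 2, 0.06 without Model 3 and 0.10 without MAN@SKI II 1. The synaptic genes Dlg4 (0.12 ± 0.09) and Syn1 (0.14 ± 0.08) and the neurotrophin Bdnf (-0.11 ± 0.11) were not called. In the excitatory postsynapse list 0 of 32 genes were called by edgeR and limma-voom and 1 by DESeq2, with 4 at an unadjusted p under 0.05, and 1 rose when adjusted over the list alone (camera adjusted p = 0.152).

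Besides the immediate early genes, 7 lists were called by camera between MAN@SKI II and Model, and 0 of the 8 with an estimated correlation or by fry. Mitochondrially encoded genes were higher, with 13 of 13 positive, a median of 0.35 and 2 that rose when adjusted over the list alone, mt-Nd3 and mt-Co2 (camera adjusted p = 3.05e-10, and adjusted p = 0.522 with an estimated correlation). The median was 0.12 without MAN@SKI II 2, the library with 9.63% mitochondrial counts, and mt-Nd3 has a near-identical nuclear copy. Dentate gyrus genes had a median of 0.18 (adjusted p = 0.0410, and adjusted p = 0.747 with an estimated correlation), and the call was lost without Con 2 (0.0528), Model 2 (0.875, median 0.07), MAN@SKI II 2 (0.0978, median 0.06) or MAN@SKI II 3 (0.134). Oligodendrocyte progenitor genes had a median of -0.25 (adjusted p = 0.00208, and adjusted p = 0.522 with an estimated correlation), lost without Model 2 (median -0.13, 0.109). Endothelial genes, 13 of 15 of them negative, had a median of -0.16 (adjusted p = 0.00208, and adjusted p = 0.361 with an estimated correlation), lost without Model 2 (0.0576). Blood cell genes, which are hemoglobins and Alas2, had a median of -0.86 (adjusted p = 0.00208, and adjusted p = 0.747 with an estimated correlation), lost without MAN@SKI II 2 (median -0.45, 0.0978). Nuclear-encoded respiratory chain genes had a median of -0.09 (adjusted p = 0.00585, and adjusted p = 0.747 with an estimated correlation), which was -0.22 without MAN@SKI II 3 and turned to 0.03 without MAN@SKI II 2 (0.622). Myelin genes, of which 1 fell when adjusted over the list alone, had a median of -0.12 (adjusted p = 0.0164, and adjusted p = 0.747 with an estimated correlation). That call was lost without Model 2 (median -0.05, 0.385), MAN@SKI II 1 (0.0770) or MAN@SKI II 2 (median -0.03, 0.0978), and the median was -0.19 without Model 1 and -0.20 without Model 3. In the other 5 of these lists 0 genes changed when adjusted over the list alone. The list count of 8 was 4 without MAN@SKI II 2.

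**Figure D3:**
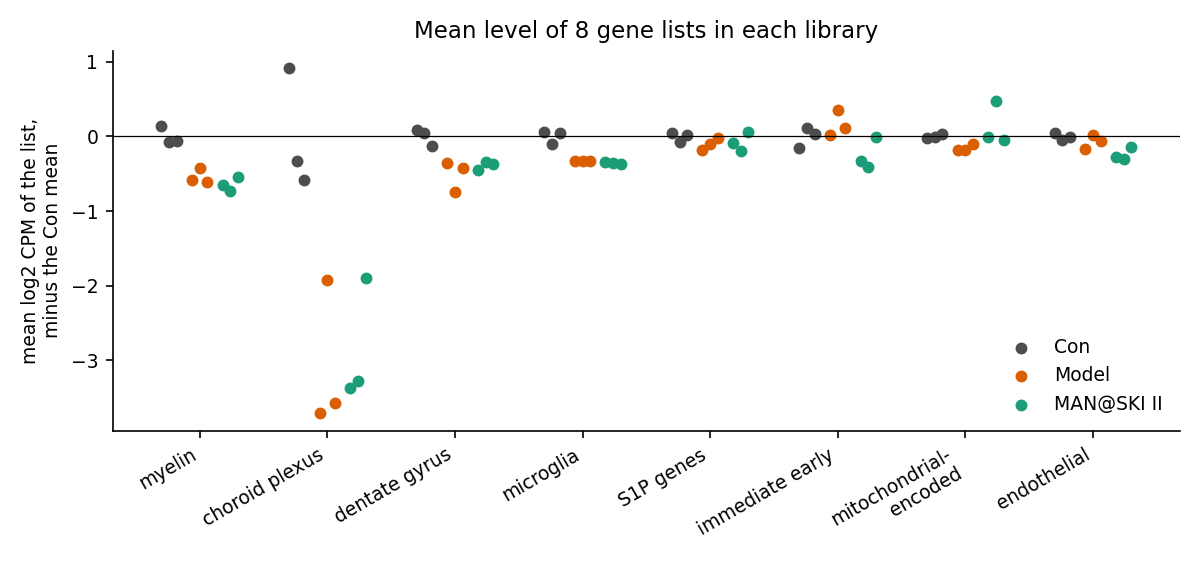
Mean log2 CPM of 8 gene lists in each library, minus the mean of the 3 Con libraries (points, 1 per library, coloured by group). Myelin and microglial genes lay below the Con libraries in all 6 BTBR libraries, choroid plexus genes were lowest in 4 of the BTBR libraries, and MAN@SKI II 2 had the highest mitochondrially encoded level.

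The comparison of MAN@SKI II with Con asked which differences from the control strain were present in treated mice. The genes with the largest rises were those of the Model comparison: Lgr6 (2.58 ± 0.11), Pla2g4e (2.11 ± 0.10), Cfap54 (2.01 ± 0.17), Serpina3n (1.92 ± 0.08), Dnah6 (1.87 ± 0.23) and Abhd1 (1.81 ± 0.12), where Cfap54 and Dnah6 encode axonemal proteins of cilia. Gabra2 rose from 96.7 ± 9.10 to 232 ± 56.2 CPM. Mobp fell from 1166 ± 100.3 to 491 ± 20.7 CPM and C1qb from 34.6 ± 1.61 to 15.4 ± 1.57 CPM (SD, n = 3 each). C1ql2, a synaptic organiser of dentate granule cells, fell from 81.1 ± 4.87 to 38.3 ± 5.74 CPM, and Nrgn, neurogranin, a postsynaptic calmodulin-binding protein, fell by 0.38 on the log2 scale. Both were also below all Con libraries in Model 1 to 3, with C1ql2 at 42.8, 31.3 and 45.6 CPM and Nrgn at 885, 852 and 881 CPM. By edgeR 602 genes were higher and 825 lower in MAN@SKI II at an adjusted p under 0.05. The count of 1427 was 857 without Con 1, 878 without Con 2, 944 without Con 3, and 149 under the choroid plexus covariate.

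Of the S1P genes, S1pr5, an S1P receptor of oligodendrocytes, fell from 18.7 ± 0.717 CPM in Con to 14.1 ± 1.302 CPM in MAN@SKI II (log2 fold change -0.40 ± 0.10, adjusted p = 0.0317). It was the 1 gene of 14 called, and the list was not called (camera adjusted p = 0.636). The S1pr5 call was lost without Con 1 (adjusted p = 0.0952), Con 2 (0.119), Con 3 (0.0686), Model 1 (0.0514), Model 3 (0.0502), MAN@SKI II 1 (0.0892) or MAN@SKI II 2 (0.0554), and its value of -0.17 ± 0.10 against Model was not called. Bdnf fell from 45.3 ± 3.66 to 33.1 ± 3.71 CPM (adjusted p = 0.0230), a call lost without Con 2 (0.0834), Con 3 (0.0924) or MAN@SKI II 1 (0.0818) and with the 6 compared libraries alone (0.0526). Apoe had a value of 0.22 ± 0.21 (adjusted p = 0.611), and Sphk1, Sphk2, Sgpl1, S1pr1, S1pr2 and S1pr3 were not called. Draxin fell to 0.771 ± 0.308 CPM.

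By camera 8 lists were called between MAN@SKI II and Con, and 0 with an estimated correlation. By fry 9 lists were called, 6 of them among these 8. Of 15 myelin genes 10 fell, and 13 fell when adjusted over the list alone (median -0.62, adjusted p = 5.12e-17, and adjusted p = 0.213 with an estimated correlation). Of 19 microglial genes 6 fell, and 8 fell when adjusted over the list alone (median -0.24, adjusted p = 4.54e-05, and adjusted p = 0.213 with an estimated correlation). Of 15 choroid plexus genes 8 fell, and 14 fell when adjusted over the list alone (median -3.11, adjusted p = 2.06e-09, and adjusted p = 0.469 with an estimated correlation), with the Ttr levels per library given above. Of 10 dentate gyrus genes 3 fell, and 4 fell when adjusted over the list alone (median -0.28, adjusted p = 0.00136, and adjusted p = 0.543 with an estimated correlation). Of 10 oligodendrocyte progenitor genes 3 fell, including the transcription factor Olig1 at -0.44 ± 0.09, and 6 fell when adjusted over the list alone (median -0.34, adjusted p = 0.00658, and adjusted p = 0.469 with an estimated correlation). The progenitor call was lost under the choroid plexus covariate (median -0.09, adjusted p = 0.844). Of 13 glucocorticoid-responsive genes 4 fell, and 1 rose and 7 fell when adjusted over the list alone (median -0.38, adjusted p = 0.0258, and adjusted p = 0.732 with an estimated correlation). That call was lost without Con 2 (0.0735) or MAN@SKI II 2 (0.0511), and its median was -0.58 without Con 3. The 3 tested genes with known BTBR variants had a median of -0.83, with 1 that fell and 3 that fell when adjusted over the list alone (adjusted p = 0.0323, and adjusted p = 0.469 with an estimated correlation), lost without MAN@SKI II 3 (0.0695). Of 15 GABA receptor genes 2 rose, and 2 rose when adjusted over the list alone (median 0.12, adjusted p = 0.0404, and adjusted p = 0.732 with an estimated correlation). The GABA receptor call was lost without Con 1 (0.123), Con 2 (0.0538), Model 2 (0.0507) or MAN@SKI II 2 (median 0.02, 0.353). It was also lost by fry (fry adjusted p = 0.208) and under the choroid plexus covariate, where the median was -0.04 (0.999). The median was 0.19 without MAN@SKI II 3. The list count of 8 was 13 without MAN@SKI II 3.

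Both BTBR groups differed from Con in many of the same genes. Of the genes called, 433 were higher and 604 lower in both comparisons and 0 were called in opposite directions, where independent lists of these sizes would share 18.7 and 37.3. The fold changes of the 17550 genes correlated at r = 0.891 with a covariance of 0.411, across genes, which are not independent replicates. Simulated groups that shared a Con group and did not differ gave 0.499 and 0.0437. Simulations with the strain difference and no treatment effect shared 461 to 517 higher and 650 to 709 lower genes. Their fold changes correlated at 0.901 to 0.920, with covariances of 0.467 to 0.500. The observed values lay below all these ranges, although the simulations also called more genes between Model and Con (1598 to 1750). These simulations took the observed group means, sampling noise included, as the true strain difference and then added noise again. That can raise their shared calls, correlations and covariances by construction, so no conclusion is drawn from the gap. The 3 Con libraries could not be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls.

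**Figure D4:**
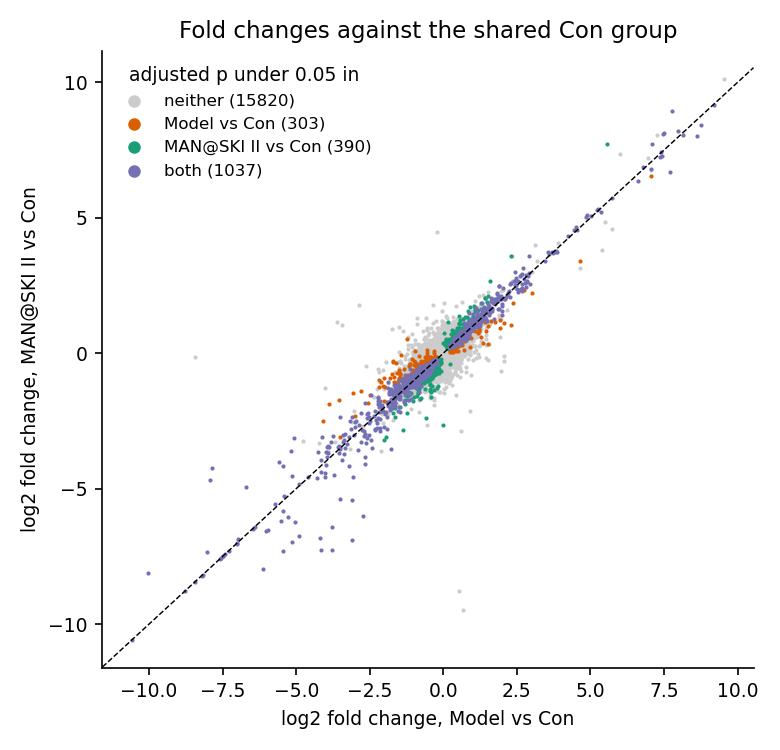
Log2 fold change of each gene tested in Model against Con (x axis) and in MAN@SKI II against Con (y axis), coloured by the comparison in which its adjusted p was under 0.05, with the line of equal change dashed. The 1037 genes called in both comparisons lie along the line, beside 303 called in Model alone and 390 in MAN@SKI II alone.

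Whether treatment moved the strain differences back was measured over the 1340 genes called between Model and Con. Of these, 791 (59.0%) had a fold change of the opposite sign in MAN@SKI II against Model. By edgeR 0 were called in both comparisons with opposite signs, since it called 0 genes in the treatment comparison at all. The 2 comparisons share the Model libraries, and simulations with the strain difference and no treatment effect gave opposite signs for 61.4% to 66.6% of called genes (mean 64.4%). The observed 59.0% lay below this range, so it was no larger than sharing the Model libraries alone gave in these simulations. Across genes the fold changes correlated at r = -0.174 with a covariance of -0.0370, against simulated means of -0.208 and -0.0464 with no treatment effect and of -0.491 and -0.0428 with no difference between any groups. The count of 791 was 472 without Con 1 (56.9% of the strain genes called), 515 without Con 2 (58.5%) and 1396 without MAN@SKI II 2 (62.7%).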

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

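The alternatives with a choroid plexus covariate and with near-identical genes summed or left out were chosen after seeing the data, and the others were planned. Of 53 named genes called in Model against Con, 11 were called under all 20 other gene-level settings without a fold change threshold, and of 59 in MAN@SKI II against Con, 13 were. Most of these losses came with the covariate: in Model against Con it ended 40 of the 53 calls, against 10 to 15 when a Con or Model library was left out. Scaling moved the median gene by at most 0.022. RLE factors, the stricter filter and limma-voom left the counts of called genes within 1.5 times in every comparison. The choroid plexus covariate runs with strain, which widens the errors of both strain comparisons by construction. It can also take up part of the strain differences themselves. The threshold of 1 on the log2 scale lowers counts by construction, and for the other changes the cause was not tested.

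Genes called between Model and Con numbered 2073 with the 6 compared libraries alone, 566 at an absolute log2 fold change of at least 1, 124 with the covariate, and 830 to 2226 with 1 library left out. Between MAN@SKI II and Model they numbered 1 with no factors, 1 with no filter, 17 by DESeq2, 1 with the 6 compared libraries alone, and 0 to 9 with 1 library left out. Between MAN@SKI II and Con they numbered 572 at the log2 threshold, 149 with the covariate, and 857 to 1633 with 1 library left out. Called lists numbered 0 with an estimated correlation in each of the 3 comparisons. By fry they numbered 6 in Model against Con, 4 of them among the 5 called by camera. They numbered 0 by fry in MAN@SKI II against Model. In MAN@SKI II against Con they numbered 9 by fry, 6 of them among the 8 called by camera. With 1 library left out, camera called 4 to 10 lists in MAN@SKI II against Model and 6 to 13 in MAN@SKI II against Con. Strain genes that moved the other way with treatment numbered 322 at the log2 threshold, 73 with the covariate, 0 if called in both, and 472 to 1396 with 1 library left out. Their share of the strain genes called changed less: 59.0% in the main fit, 56.9% at the log2 threshold, 58.9% with the covariate, and 55.6% to 63.1% with 1 library left out.

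Directions turned as follows. With the covariate the values were 0.49 for the ependymal list (Model against Con), 0.013 for the choroid plexus list in Model against Con and -0.30 in MAN@SKI II against Con (where its test direction turned), -0.041 for the GABA receptor list (MAN@SKI II against Con), -0.11 for Syn1 (Model against Con), -0.0022 for Apoe and 0.032 for Draxin (MAN@SKI II against Model), and 0.25 for Sphk2, 0.080 for Sgpl1, 0.52 for S1pr2 and -0.048 for Dlg4 (MAN@SKI II against Con). The covariate is the mean of the choroid plexus list itself, so the change of that list is taken out by construction. Its turned directions are therefore not a result about these genes. Summed families gave 0.056 for Rpl14 and 0.55 for Rpl29 (Model against Con) and 0.53 for Rpl29 (MAN@SKI II against Con). With limma-voom S1pr2 was at -0.065 (Model against Con) and 0.0012 (MAN@SKI II against Model), and Apoe at -0.020 (MAN@SKI II against Model). Sphk2 in MAN@SKI II against Con was at 0.0011 with RLE factors and 0.0023 with DESeq2. With 1 library left out, values in Model against Con ranged from -0.78 to 0.020 for Sphk1, -0.058 to 0.061 for Sgpl1 and -0.21 to 0.27 for S1pr2. In MAN@SKI II against Model they ranged from -0.22 to 0.031 for the nuclear-encoded respiratory chain list, -0.17 to 0.22 for Apoe, -0.093 to 0.28 for Sphk1, -0.13 to 0.091 for Sgpl1, -0.021 to 0.058 for S1pr1, -0.32 to 0.17 for S1pr2, -0.00012 to 0.089 for S1pr3, -0.31 to 0.30 for Draxin and -0.26 to 0.015 for Itpr3. In MAN@SKI II against Con they ranged from -0.72 to 0.082 for Sphk1, -0.073 to 0.048 for Sphk2, -0.13 to 0.098 for Sgpl1 and -0.23 to 0.10 for S1pr2.

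The data gave no sign that the replicate numbers of the titles pair the mice: over the 9 pairs of libraries that share a number, deviations from the group means correlated at -0.0639 to 0.0525, 0 of 9 were over 0.1, and 2 of 9 libraries correlated best with their own number. With so few libraries per group a pairing cannot be excluded. The numbers in the library names differ in part from the replicate numbers, and a pairing by them was not tested. The dentate gyrus list in MAN@SKI II against Model lost its call with the replicate block (adjusted p = 0.0651). With the number as a replicate block, 1044, 1 and 1134 genes and 5, 7 and 8 lists were called in Model against Con, MAN@SKI II against Model and MAN@SKI II against Con, and 609 strain genes moved the other way with treatment. Sgpl1 and S1pr2 in Model against Con took -0.00020 and -0.024 with the replicate block.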

Other observations

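The tests of the choroid plexus genes across Model libraries and of summed gene families were chosen after the results were seen, as was the use of the planned fits with an estimated correlation and without MAN@SKI II 2 as tests of an explanation and the simulation of shifted lists, and the tests of all called genes for copies, of transcript length, of neighbouring genes and of sample splits were chosen before. A few genes of mural cells and of the striatum differed between Model and Con, although neither list was called. Among 10 mural cell genes, Abcc9, a subunit of the vascular ATP-sensitive potassium channel, rose from 8.78 ± 0.357 CPM in Con to 15.1 ± 0.468 CPM in Model (SD, n = 3), and Rgs5, a pericyte regulator of G-protein signalling, fell from 103 ± 4.79 to 66.8 ± 5.39 CPM. The mural list was not called (camera adjusted p = 0.512). Rgs9, a regulator of G-protein signalling best known from the striatum, fell from 16.7 ± 0.755 to 7.12 ± 1.05 CPM in Model and to 7.40 ± 1.13 CPM in MAN@SKI II, and 2 of 11 striatal genes fell in Model (camera adjusted p = 0.393). Lists of thalamic (adjusted p = 0.674) and cortical genes (adjusted p = 0.909) were not called between Model and Con.

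The clock gene list was not called by camera in any comparison. By fry it was called as higher in MAN@SKI II against Con (fry adjusted p = 0.0422). Of 14 genes tested, 1, Per3, rose in Model against Con, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.269 for the list). The Per3 call was lost without Con 1 (0.0976), Con 3 (0.0939), Model 1 (0.0776) or Model 3 (0.103) and under the choroid plexus covariate (0.946). In MAN@SKI II against Con 3 rose, and 6 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.115). Nr1d1, a nuclear receptor that represses clock transcription, was at 81.9 ± 2.15 CPM in Con, 100.2 ± 13.1 CPM in Model (not called, adjusted p = 0.160) and 118 ± 16.3 CPM in MAN@SKI II, a call against Con lost without Con 1 (adjusted p = 0.0609) or Con 2 (0.0576). Between MAN@SKI II and Model 0 clock genes were called by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05 (list median 0.0084, camera adjusted p = 0.510). Genes called between Model and Con also clustered along chromosomes, counting only tested genes with no near-identical copy found. In windows of 5 Mb on GRCm39 with at least 15 such genes, 12 of 42 were called on chromosome 4 from 145000001 to 150000000, which holds Draxin, and 8 of 21 on chromosome 12 from 20000001 to 25000000. Of all such genes 7.31% were called. These windows were chosen after their values were seen. Genes that were not in the searched annotation, or that have less similar copies, count here as having no copy.

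Choroid plexus genes were on average higher in all 3 Con libraries than in all 6 BTBR libraries, and within the BTBR groups Ttr was high in Model 2 (257 CPM) and MAN@SKI II 3 (313 CPM). Unequal amounts of choroid plexus carried over at dissection are a candidate explanation for the spread within a group: 14 of the 14 other members were higher in Model 2 than in both other Model libraries, where 33.3% would be by chance and 34.8% of all genes were, although these genes are not independent of each other. In MAN@SKI II 3, 12 of the 14 were. For the gap between the strains, carry-over and a strain difference in the choroid plexus itself both stay open, since every Con library is on one side. The design gives the strain as a biological explanation, which was not tested apart from the dissection.

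The genes called between Model and Con may hold several kinds of difference. Reads shared with the near-identical copies that were found cannot account for most of the calls, since 14.6% of called genes have such a copy, against 10.9% of all genes tested. These shares are lower bounds: the 1860 genes with counts that were not in the annotation, and genes with less similar copies, were counted as having none. Among the 196 that do, 107 (54.6%) lie in families that are not called once counts are summed, so shared reads may account for these. Called genes with no copy found were adjacent in 132 pairs, against 72.3 when calls were shuffled within chromosomes (permutation p = 1e-04, the smallest that 10000 shuffles can give), whereas as many genes with the smallest p in MAN@SKI II against Model gave 74 pairs (73.4 shuffled, permutation p = 0.5). Haplotype blocks that differ between the strains could give such neighbours. Neighbours regulated together in either strain, and reads shared among neighbouring genes whose copies were not found, stay open too. Lower mapping of BTBR reads to a reference built from C57BL/6J was not tested, because the table holds no reads.

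Of the lists called between MAN@SKI II and Model, 0 stayed called by camera with the correlation estimated per list. In simulated independent genes with these 8 lists shifted by their medians, that test called 75 of 160 shifted lists (0 of 20 draws had none called) and the preset correlation 135. Part of the loss thus comes from the test itself, and whether genes of a list that vary together between mice account for the rest stays open. At the preset correlation, 6 of 10 splits of the same libraries, the real one included, called at least as many lists as the real 8 (highest other 15). The list calls at that setting therefore do not set treatment apart from variation between mice. The library MAN@SKI II 2 alone does not account for the immediate early genes, whose median was -0.36 without it, but it may account for most of the rise in mitochondrially encoded genes, whose median of 0.353 became 0.116. In that library the longest 25% of genes deviated from the shortest 25% by 0.181 on the log2 scale, against at most 0.0796 in size in the other 8 libraries, so a transcript length bias is a candidate explanation for its distance from the rest. Whether treatment, handling, the time since behavioural testing or other variation between mice lowered the immediate early genes stays open, since the labels give no times per mouse.

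Other splits of the same libraries are too few, at 10 per pair of groups, for a share under 0.05. For genes, 1 of 10 splits gave at least as many as the real 1340 in Model against Con (highest other 5). In MAN@SKI II against Model 10 of 10 gave at least as many as the real 0 (highest other 6), which every split must, so this share tests nothing. In MAN@SKI II against Con 1 of 10 gave at least as many as the real 1427 (highest other 6). For lists, 8 of 10 splits gave as many as the real 5 (highest other 11), 6 of 10 as many as the real 8 (highest other 15) and 8 of 10 as many as the real 8 (highest other 16). Of the 20 assignments of the 6 BTBR libraries to Model and MAN@SKI II, 13 gave as large a share of strain genes moving the other way as the real 59.0% (highest other 70.1%).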
